A study of Mus musculus with 5 samples.

How the data were processed

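Total RNA of magnetically enriched B220+ bone marrow cells was labelled with biotin from 150 ng and hybridised to Affymetrix whole-genome mouse arrays, per the labels' protocols: 3 arrays of KA/KA mice and 2 of WT littermates, all at 4 weeks of age on the FVB background. The authors deposited 1 table with an intensity for each of 45101 probe sets on each array. MAS5 is named in the submitters' processing notes, without a version, and the series text speaks of normalisation and a log2 transformation. The deposited values were not on a log scale: their highest signal was 21977 to 40821, and each array had a trimmed mean of 500 (2% left out at each end), which is how MAS5 scales linear signals. They were therefore used as linear intensities, and log2(signal + 16) was computed from them, a rule fixed before the data were examined. Array medians on that scale differed by 0.37, under the limit of 0.5 set for centring, so no further scaling was done. Depth has no counterpart here; detection calls were not used here.

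Probe sets were named through the platform annotation given with the series: 34958 had 1 gene symbol, 932 had several and were left unnamed, and 9160 (20.3%) had none in that table. The 64 control probe sets were left out. The 22519 probe sets at or above the median of the mean log2 signal were kept, 19491 of them with 1 symbol, and each of the 11392 genes was represented by its probe set of highest mean; 6430 genes had a single kept probe set, and the kept probe sets of 2010 genes pointed in different directions. The transcript level of the mutated gene itself was not analysed here.

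Groups follow the labels. limma 3.58.1 in R 4.3.3 fitted a 2-group model (lmFit, then eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. With 3 against 2 arrays there are 10 splits, so an exact permutation test of a single gene could not go below 0.1 and was not run. The 28 gene lists were fixed before the data were examined; the 27 with at least 5 tested genes went into camera (preset correlation 0.01), with camera at an estimated correlation and fry beside it. For comparisons of 1 array with 1, a list's median difference was ranked among 10000 random lists matched on level, drawn with a fixed seed from genes kept by the filter in that set of arrays; such percentiles describe these arrays alone. Genes were named by a rule fixed beforehand: the largest changes among genes past the threshold with complete separation of the groups; where fewer than 5 qualified in a direction, the 5 with the smallest p; of each list the members past the threshold, or else at most 2 of smallest p (2 for called lists and 1 for others); and 14 genes of B-cell development and NF-κB. Genes named for single sets of arrays and the tissue markers were chosen after the values were seen.

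The array sets were defined from the 24 poly-A control probe sets (Dap, Lys, Phe and Thr), with a median log2 signal of 10 as the border. The labels give no batch. The array set then entered as a block, and each set was also analysed on its own; these settings were added after seeing the data.

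limma's gene test and the list tests were tried on simulated data, built with the array sets and so after the data were examined; the interaction fit and the fit on the low-spike arrays alone were not. The data were the 11392 genes at their own array-set means with independent normal noise of the spread inside the sets, 200 of them changed by 2-, 4- or 16-fold, in 20 draws. For 2-fold changes the median estimate, averaged over draws, was 1.02 (truth 1) without and 1.01 with the array-set block; the first recovered 0% of them and the second 4.85%. Calls of unchanged genes numbered 0 and 10.85 per draw. A list shifted by 1 log2 unit was called by camera in 20 of 20 draws under both fits. Without any shift, 22 of 540 list tests (no block) and 5 of 540 (block) were called at an adjusted p under 0.05. All of these calls were false. They were made after adjustment over the lists, so their share of 540 does not measure the error rate of the adjusted test. The noise was independent between genes, so these counts do not cover lists whose genes vary together. Camera with an estimated correlation called the shifted list in 0 of 20 draws under both fits, and fry in 0 of 20 without and 5 of 20 with the block, so a list lost under them is not shown to be unchanged.

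The alternatives were quantile normalisation, median centring, a floor at the 20th percentile, pseudocounts of 1 and 64, no filter and an upper-quarter filter, eBayes without trend and with robust fitting, array weights, every probe set on its own, leaving out probe sets shared between transcripts, averaging probe sets, the replicate number as a block, and leaving out each array.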

Results

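Gene expression was profiled in bone marrow cells carrying B220, a surface form of CD45 found on developing B cells, from FVB mice at 4 weeks of age. Of the 5 Affymetrix whole-genome mouse arrays, 3 were labelled as mice homozygous for a kinase-dead knock-in of IKKα (KA/KA), a kinase of the NF-κB pathway, and 2 as wild-type littermates (WT). By the labels, the comparison asks which genes depend on IKKα kinase activity while B cells are being formed. Each array gave an intensity for 45101 probe sets, scaled to a trimmed mean of 500, with medians from 95.7 to 128. Signals are given below as log2(signal + 16), a scale that understates changes of dim genes, and every array is named by its label. The number of arrays limits the precision. The labels number the mice of each array without saying whether an array holds 1 animal or a pool, so test results measure the spread between these arrays.

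The arrays fell into 2 sets, each holding arrays of both genotype labels. On the arrays labelled KA/KA 1 and WT 1, genes of V(D)J recombination and of the surrogate light chain were abundant. Rag1 read 12.80 and 12.79, Dntt 12.18 and 12.20, Igll1 12.56 and 12.99, and Vpreb1 12.74 and 13.39. On the arrays labelled KA/KA 2, KA/KA 3 and WT 2, Rag1 read 4.09, 4.09 and 4.10, which is background on this scale. Dntt (6.07, 4.22 and 5.28), Igll1 (5.85, 5.64 and 6.25) and Vpreb1 (6.0, 5.74 and 4.34) were close to it. Genes of lung epithelium ran the opposite way. Sftpc, which encodes surfactant protein C, read 15, 14.99 and 14.04 on the arrays labelled KA/KA 2, KA/KA 3 and WT 2, against 6.53 and 5.97 on those labelled KA/KA 1 and WT 1. Scgb1a1, the main secretory protein of club cells, read 15.16, 15.31 and 14.29 against 4.43 and 4.40, and Ager, a marker of flat alveolar cells, 14.06, 14.39 and 14.03 against 5.93 and 5.62.

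**Figure D1:**
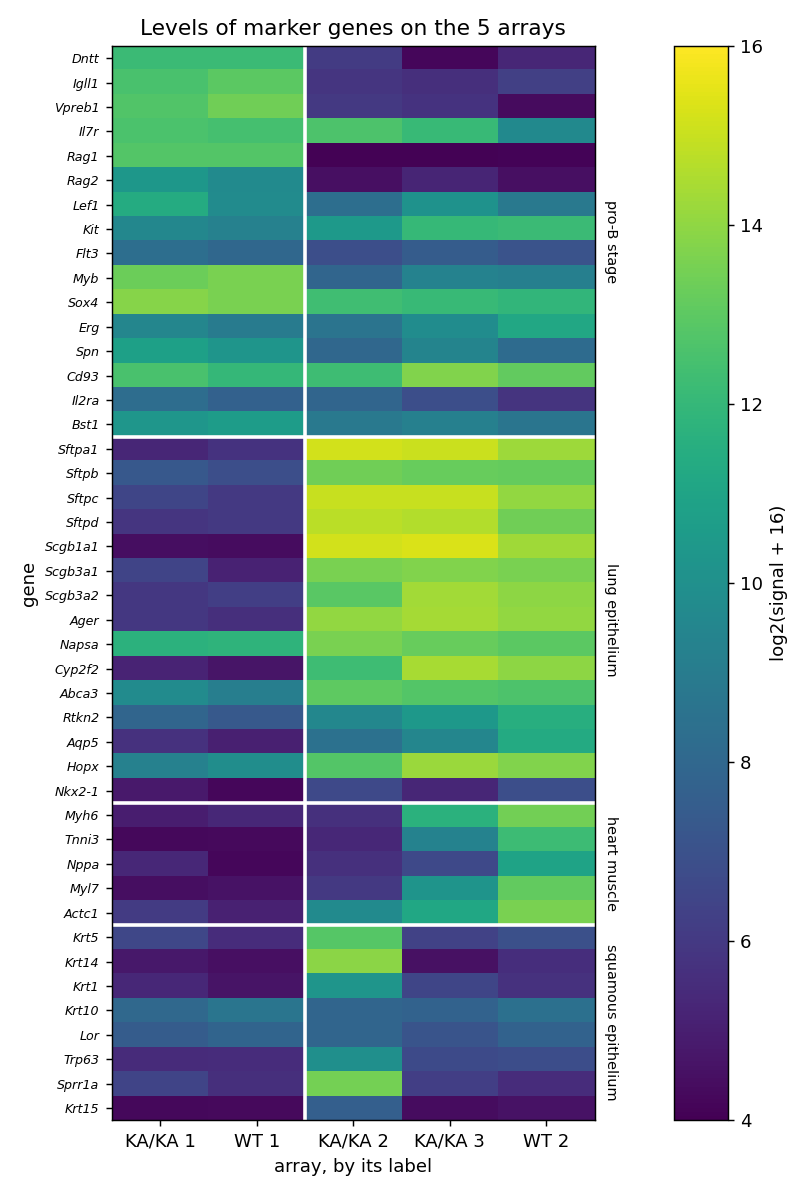
Heat map of log2(signal + 16) of the genes of 4 marker lists (y axis) on the 5 arrays (x axis, by label), with white lines between lists and between the sets of arrays. Rag1 reads 12.80 and 12.79 on the arrays labelled KA/KA 1 and WT 1 and at most 4.10 on the others, and Sftpc 6.53 and 5.97 against at least 14.04.

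Of 15 lung epithelial genes, 11 lay in the top 5% of probe sets on all of the arrays labelled KA/KA 2, KA/KA 3 and WT 2 and on neither of the others, and the list's median was 7.65 log2 units higher on those 3 arrays. The tissue marker lists were written after the split of the arrays was seen. Smooth muscle genes (median difference 5.44 over 5 genes), heart muscle genes (5.11 over 5 genes) and endothelial genes (3.69 over 10 genes) were also higher there, above all of 10000 random lists matched on level, while squamous epithelial genes (2.35 over 8 genes) and mesothelial genes (2.06 over 5 genes) stayed inside the range of such lists. The heart muscle gene Myh6 read 11.66 and 13.43 on the arrays labelled KA/KA 3 and WT 2 but 5.68 on that labelled KA/KA 2. Basal and squamous keratinocyte genes stood out on the array labelled KA/KA 2 alone, where Krt14 read 13.90 against 4.53 and 5.56 on the arrays labelled KA/KA 3 and WT 2, and Sprr1a 13.52 against 6.24 and 5.52. Kidney (0.70), skeletal muscle (0.61), brain (0.31), liver (0.29), bone (0.0002), intestine (-0.03) and adipose (-0.40) markers differed by less than 1 log2 unit in the median. Among lists fixed before the data were examined, proliferation (-3.91), neutrophil granule (-3.20), pan-B and B cell receptor (-2.91) and early B transcription factor genes (-2.74) were lower on the arrays labelled KA/KA 2, KA/KA 3 and WT 2.

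The same sets appeared in the poly-A control signals, which carry no mouse RNA. The 24 probe sets for bacterial poly-A transcripts, which are added to RNA before labelling, had a median signal of 11874 and 7301 on the arrays labelled KA/KA 1 and WT 1 and of 136, 249 and 46.9 on those labelled KA/KA 2, KA/KA 3 and WT 2. Across 11392 genes, Pearson's r between arrays was 0.840 to 0.967 inside the sets and 0.451 to 0.578 between them (genes are not independent replicates). The closest pair of all was KA/KA 1 with WT 1 (r = 0.967), and the first principal component, which separated the sets, held 83.0% of the variance. Actin 3' to 5' signal ratios were 1.21 to 1.41 on all arrays. The BioB control signal did not divide the arrays in this way (717 and 1107 against 837, 882 and 406, in the same order). The 18S rRNA signal did (5044 and 9913 against 809, 763 and 138). Below, the pair with high control signal (labelled KA/KA 1 and WT 1) is called the high-spike pair and the other 3 arrays the low-spike arrays; these sets were defined from control probes and are not groups of the study.

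The comparison of genotypes over all arrays spans the pair with B-lineage genes and the arrays with lung epithelial genes. It therefore cannot tell which genes depend on IKKα kinase activity in B cells. In this comparison, the genes of smallest p were Ms4a4b, Slc7a8 and Ccl8 upward and Hbb-b2 downward, none of which passed the test. Ms4a4b, a membrane protein of lymphocytes, differed by 5.19 ± 0.93 log2 units (KA/KA minus WT, ± SE, n = 3 and 2), from 4.19 and 4.18 on the WT arrays to between 8.23 and 10.96 on the KA/KA arrays. The WT values are background, so the size depends on the constant added (3.46 with 64 in place of 16). The amino acid transporter Slc7a8 (2.00 ± 0.36), the chemokine Ccl8 (4.41 ± 1.11), the atypical IκB protein Bcl3 (1.67 ± 0.46) and the lysosomal phosphatase Acp2 (0.99 ± 0.31) followed. Lower values were seen for the β-globin Hbb-b2 (-1.52 ± 0.31), the mitochondrial genes Atp5md (-0.89 ± 0.27), Fmc1 (-0.93 ± 0.37) and Cox6a2 (-1.41 ± 0.58) and the vesicle gene Vamp5 (-0.87 ± 0.33). All 3 KA/KA arrays lay on one side of both WT arrays for each of these 10 genes. For Hbb-b2 and Vamp5, 1 of 2 probe sets pointed the other way. Cox6a2 differed by -2.73 and -1.80 on the low-spike arrays (KA/KA 2 and KA/KA 3 minus WT 2) but by -0.32 in the high-spike pair. Heart muscle genes were lower on the same low-spike KA/KA arrays, and whether Cox6a2 follows them was not tested.

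No gene passed limma's test over the 5 arrays: 0 of 11392 genes were higher and 0 lower at an adjusted p of 0.05, and the smallest adjusted p was 0.9999. That was the value for every gene named here. At an unadjusted p under 0.05 there were 25 genes (22 higher and 3 lower), where chance gives 569.6 if the arrays are interchangeable. Complete separation of the groups occurred for 469 higher (4.12%) and 303 lower genes (2.66%), where chance gives 10% in each direction on the same condition. The array sets break that condition: each set held a WT array, so a gene split by set cannot separate the groups. Neither count therefore shows that genotype differences are rarer than chance. In simulated data with the means of the array sets, the spread inside them and 200 changed genes, this fit recovered 0% of 4-fold and 0.303% of 16-fold changes. With the array set as a block, a setting chosen after seeing the data, limma again called 0 genes higher and 0 lower. It gave 311 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.9989. The same simulation recovered 72.2% of 4-fold and 98.3% of 16-fold changes under the block. It held 200 changed genes and independent normal noise, so these shares do not show that such changes are absent. Under the block Slc7a8 stood at 2.04 ± 0.28 and Ms4a4b at 5.13 ± 0.82 without passing.

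**Figure D2:**
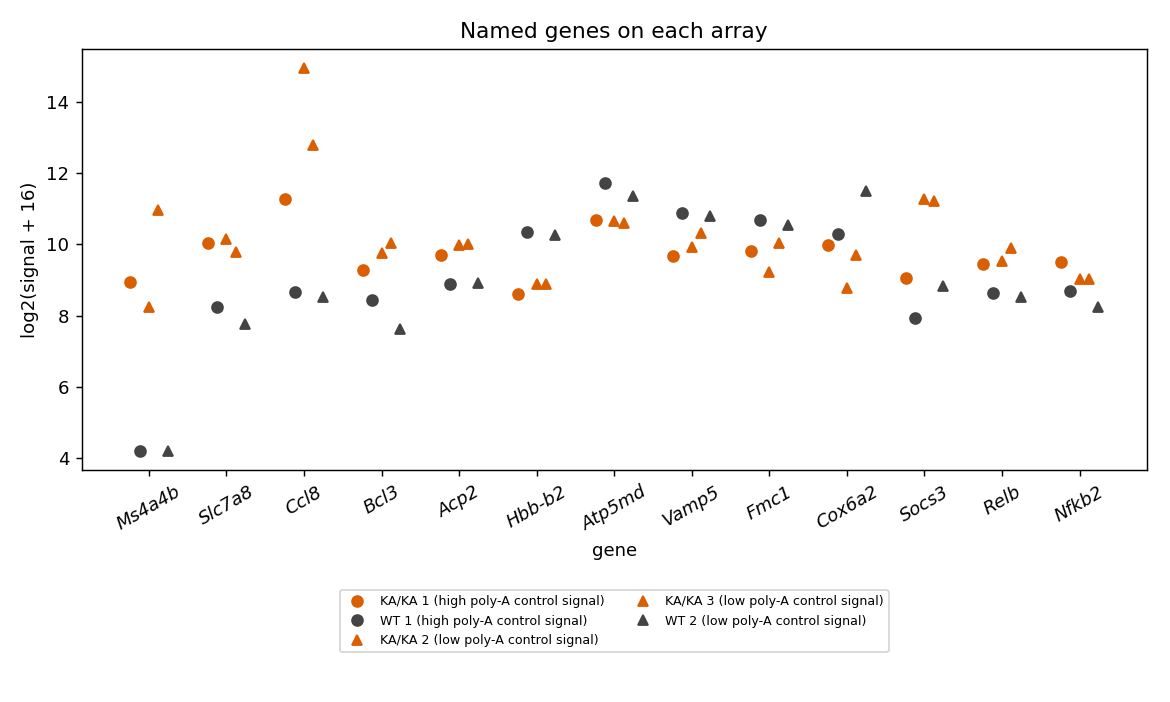
Log2(signal + 16) of 13 named genes on each of the 5 arrays, with KA/KA arrays in orange, WT arrays in grey, circles for the high-spike pair and triangles for the low-spike arrays. Ms4a4b reads 4.19 and 4.18 on the WT arrays and at least 8.23 on the KA/KA arrays, and Hbb-b2 10.34 and 10.28 against at most 8.89.

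NF-κB target genes lay higher on the KA/KA arrays as a group, mainly through the low-spike arrays. Of 25 measured, 23 had a higher mean, with a median difference of 0.74 (camera in limma, adjusted p = 9.1e-10; adjusted p = 0.385 with an estimated correlation). Of the NF-κB pathway components, 17 of 23 were higher (median 0.31, adjusted p = 0.00158; 0.385 as the adjusted p with an estimated correlation). Both lists differed mainly in the low-spike arrays (medians 0.80 and 1.31 for targets, 0.17 and 0.58 for components). On these arrays, where lung epithelial genes were high, lists of other cells were higher as well. Medians were 2.03 and 1.49 for monocyte and macrophage, 1.27 and 2.15 for neutrophil granule and 0.91 and 1.98 for T cell genes. NK cell genes were not higher (-0.52 and -0.07). Whether the NF-κB lists follow the mix of cells was not tested. In the high-spike pair 14 of 25 targets were higher (median 0.11, percentile 71.3) and 13 of 23 components (median 0.06, percentile 46.3). With 1 array left out the adjusted p of the components reached 0.845. Relb, the partner of p52 in the alternative pathway that IKKα activates, differed by 1.06 ± 0.34, Nfkb2, which encodes p100 and p52, by 0.72 ± 0.38, and Rela, of the classical pathway, by 0.37 ± 0.52. Relb and Nfkb2 were above both WT arrays on all 3 KA/KA arrays, and Rela was not.

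Genes of signalling downstream of the interleukin 7 receptor lay in the same direction, with 14 of 16 higher (median 0.65). Camera gave an adjusted p of 6.9e-05, and of 0.385 with an estimated correlation. Only transcripts were measured, so activity of this pathway is not shown. The cytokine-induced inhibitor Socs3 differed by 2.13 ± 0.83 and the cyclin Ccnd2 by 0.88 ± 0.45, and both were above the WT arrays on all KA/KA arrays. Il7r itself differed by 1.36 ± 0.86. Lists of other blood cells were higher too. Monocyte and macrophage genes were higher for 17 of 19 (median 0.88, camera adjusted p = 1.1e-08; 0.385 as adjusted p with an estimated correlation), with Csf1r at 0.88 ± 0.32 and Mpeg1 at 1.16 ± 0.45. In the high-spike pair 11 of 19 were higher (median 0.04), and without the array labelled WT 2 the test pointed down (adjusted p = 0.845). T cell genes were higher for 12 of 14 (median 0.98, camera adjusted p = 7.9e-05; adjusted p = 0.556 with an estimated correlation), with Cd5 at 1.75 ± 1.05 and Lat at 0.71 ± 0.48. In the high-spike pair, however, 6 of 9 T cell genes were lower (median -0.08, percentile 22.2). Conventional dendritic cell genes were higher for 8 of 9 (median 1.20, camera adjusted p = 0.00903; adjusted p = 0.385 with an estimated correlation), with Fscn1 at 2.37 ± 1.10 but Cd209a at -1.04 ± 0.47. In the high-spike pair 3 of 6 were higher (median 0.05, percentile 38.3). C/EBP and myeloid transcription factors were higher for 9 of 11 (median 0.38, camera adjusted p = 0.0217, and adjusted p = 0.385 with an estimated correlation), with Egr1 at 1.04 ± 0.35 and Egr2 at 1.73 ± 0.97. With 1 array left out the camera adjusted p reached 0.809 for this list and 0.134 for interleukin 7 signalling genes. Erythroid genes were lower for 12 of 13 (median -0.86, camera adjusted p = 0.00880; adjusted p = 0.683 with an estimated correlation), with Alas2, the first enzyme of haem synthesis in red cells, at -1.11 ± 0.72 and Trim10 at -0.88 ± 0.94. The low-spike medians of this list were 0.05 and -0.20, and with the array set as a block its median was -0.11.

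In all, camera called 8 of 27 lists with a preset correlation of 0.01 (7 up and 1 down). With an estimated correlation, and with fry, 0 were called. The smallest adjusted p was then 0.385 and 0.190. No list held a gene past the threshold, adjusted over the list alone or over all genes. In simulated data a list shifted by 1 log2 unit was found by neither of these tests in any of 20 draws. Camera at the preset correlation found it in all 20. Without any shift and without a block, that camera test falsely called 22 of 540 lists at an adjusted p under 0.05. The simulated noise was independent between genes. With the array set as a block, the estimated correlation of the 8 called lists ran from -0.06 (interleukin 7 signalling) to 0.62 (T cell genes). The simulation therefore does not show how reliable the preset calls are for lists whose genes vary together. For 3 of the 8 called lists the median difference between the sets of arrays, over the tested genes, was larger than that between genotypes. T cell genes were 1.77 and conventional dendritic cell genes 2.29 log2 units higher on the low-spike arrays, and erythroid genes were lower (-2.07). For the other 5 the median difference between the sets was smaller, from 0.00473 for NF-κB components to 0.43 for NF-κB targets and -0.43 for monocyte and macrophage genes. For C/EBP and myeloid factors it was almost equal (0.378 against 0.385). Single members shifted far in both directions, from -4.31 to 2.49 for NF-κB components and from -3.03 to 3.52 for C/EBP and myeloid factors. A small median therefore does not mean that a list was alike in both sets.

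B-lineage lists passed no list test over the 5 arrays without a block. Early B transcription factors were higher for 10 of 18 genes (median 0.02, camera adjusted p = 0.848). With the array set as a block their median was 0.50 and camera called them (adjusted p = 0.000576; adjusted p = 0.587 with an estimated correlation), and it called pan-B genes (adjusted p = 0.00688; adjusted p = 0.588 with an estimated correlation). Pro-B stage genes were higher for 7 of 15 (median -0.04, adjusted p = 0.855) and pan-B and B cell receptor genes for 7 of 15 (median -0.24, adjusted p = 0.646). Counts of higher genes were similar for immature to mature B genes, 9 of 20 (median -0.10, mean 0.03, adjusted p = 0.855), and MHC class II genes, 4 of 9 (median -0.07, adjusted p = 0.855). The count was lowest for V(D)J recombination and end-joining genes, 2 of 10 (median -0.24, adjusted p = 0.176). In the fit without a block, single regulators of the lineage had errors as large as their differences: Ebf1 -0.86 ± 1.60, Pax5 -0.52 ± 1.33, Tcf3 -0.49 ± 1.61, Ikzf1 0.62 ± 1.43, Foxo1 0.29 ± 0.53, Spi1 0.57 ± 0.68, Rag1 -1.45 ± 3.89, Igll1 -1.60 ± 3.04 and Vpreb1 -0.71 ± 3.52. That fit ignores the array sets, and with the block sizes, errors and some signs changed. Values were then -0.28 ± 0.42 for Ebf1, -0.08 ± 0.53 for Pax5, 0.10 ± 0.33 for Tcf3, 1.12 ± 0.48 for Ikzf1 and 0.42 ± 0.37 for Foxo1. Spi1 stood at 0.78 ± 0.36, Rag1 at -0.002 ± 0.33, Igll1 at -0.47 ± 0.28 and Vpreb1 at 0.60 ± 0.53, and none passed. Rag2 fell below the filter on dim probe sets. Without the block, the smallest p of each list belonged to Id2 (0.72 ± 0.41), Il7r, Ptprc (0.39 ± 0.65), Fcgr2b (1.81 ± 1.07), Ciita (0.57 ± 0.56) and Xrcc6 (-0.69 ± 1.45).

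The remaining lists did not pass the preset camera test over the 5 arrays without a block either. Apoptosis regulators (14 of 17 higher, median 0.24, adjusted p = 0.0781), plasma cell genes (9 of 10, 0.29, 0.0711), immediate early and stress genes (14 of 20, 0.27, 0.0900) and mast cell, basophil and eosinophil genes (4 of 5, 0.56, 0.222) leaned up. NK cell (4 of 10 higher, median -0.20, adjusted p = 0.0781), plasmacytoid dendritic cell (5 of 12, -0.39, 0.0890), interferon response (5 of 14, -0.11, 0.0900) and megakaryocyte genes (2 of 9, -0.38, 0.222) leaned down. Proliferation (13 of 28 higher, median -0.03, mean 0.02, adjusted p = 0.644), neutrophil granule (10 of 20, median -0.06, mean 0.01, 0.488), stem and progenitor (7 of 11, median 0.14, 0.993), stromal (7 of 12, median 0.24, 0.488) and unfolded protein response genes (8 of 14, median 0.03, 0.742) gave no direction in this fit; the camera test of the neutrophil list pointed up and those of the stem cell and stromal lists down, against their medians. With the array set as a block, camera called proliferation (median 0.67, adjusted p = 6.5e-12; adjusted p = 0.587 with an estimated correlation), neutrophil (0.0354; 0.706 with it), plasma cell (0.0354; 0.691) and mast cell genes (0.0418; 0.587) up. It called stromal (0.0452; 0.588) and interferon response genes (0.0452; 0.587) down. The leading members of the remaining lists were Bcl2l11 (0.34 ± 0.29), Derl3 (1.19 ± 0.67), Epx (1.56 ± 1.16), Klrk1 (-0.93 ± 0.65), Ifit2 (-0.72 ± 0.55), Itgb3 (0.65 ± 0.54), Pcna (-0.32 ± 0.81), Lcn2 (1.62 ± 1.12), Mycn (0.56 ± 0.42), Adipoq (-2.56 ± 1.42) and Calr (0.43 ± 0.38), with Cox6a2 and Egr1 as above.

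The high-spike pair carried the B-lineage genes, but neutrophil granule genes were abundant as well. Of these, 12 of 20 lay in the top 5% of probe sets on both arrays, and S100a8 read 14.71 and 15.31. The mix of cells on each array was not measured. Inside this pair, regulators of early B cells were slightly higher on the array labelled KA/KA 1 than on that labelled WT 1. Foxo1 was higher by 1.06, Tcf3 by 0.61, Ebf1 by 0.57 and Pax5 by 0.41 log2 units, and Lef1, a transcription factor of pro-B cells, by 1.61, while Igll1 (-0.43) and Vpreb1 (-0.65) were lower and Rag1 was level (0.01). With 1 array per genotype these differences have no replicate check. Early B transcription factors were higher for 15 of 18 genes (median 0.15, percentile 95.9 among 10000 random lists matched on level), and pro-B genes for 11 of 16 (median 0.25, percentile 98.8). The same held for interleukin 7 signalling genes for 14 of 17 (median 0.47, percentile 99.9). Proliferation genes were higher for 20 of 29 (median 0.18, percentile 99.3) and megakaryocyte genes for 8 of 10 (median 0.35, percentile 95.8), and monocyte and macrophage genes lay at percentile 83.9. Pan-B and B cell receptor genes were lower for 9 of 15, which was ordinary for their level (median -0.16, percentile 48.6). Some other lineages ran lower, later B cells by little more than random lists: immature to mature B genes for 16 of 20 (median -0.20, percentile 8.32), MHC class II genes for 8 of 9 (median -0.38, percentile 4.71). Also lower were neutrophil granule genes for 19 of 20 (median -0.57, percentile 0.05), plasmacytoid dendritic cell genes for 11 of 13 (median -0.60, percentile 0), and erythroid genes for 15 of 15 (median -0.53, percentile 0). Interferon response genes were lower for 11 of 15 (median -0.29, percentile 0.32) and NK cell genes for 8 of 11 (median -0.27, percentile 1.3). Mast cell, basophil and eosinophil genes were lower for 5 of 8 (median -0.27, percentile 2.85). Among the 9097 genes at or above the median level of this pair, the largest upward differences were Xist (5.99), the eosinophil granule genes Epx (2.76) and Prg2 (2.75), Ccl8 (2.59) and the macrophage receptor Vsig4 (2.27). The largest downward ones were BC147527 (-1.80), Hbb-b2 (-1.75), Ceacam10 (-1.74), Cd3d (-1.73) and Cd209d (-1.67). Among dimmer genes, Ms4a4b read 8.95 against background (4.19) on the array labelled WT 1. Slit3 read background (4.39) on the array labelled KA/KA 1 against 6.39, so the sizes of these differences are not given.

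Among the low-spike arrays, several genes of inflammation and lists of immune cells were higher on both arrays labelled KA/KA than on the array labelled WT 2. Saa3, an acute-phase protein, was higher by 6.52 and 6.25 log2 units (KA/KA 2 and KA/KA 3). The chitinase-like Chil4 was higher by 8.66 and 4.88, the neutrophil chemoattractant Cxcl2 by 3.87 and 3.83 and Ccl3 by 4.03 and 4.58. On WT 2, Chil4 (6.05), Cxcl2 (5.87) and Ccl3 (5.55) read close to background, so the sizes for these genes depend on the constant added. Monocyte and macrophage genes had medians of 2.03 and 1.49 (both at percentile 100), neutrophil granule genes 1.27 and 2.15 (both 100), NF-κB target genes 0.80 and 1.31 (both 100), proliferation genes 1.04 and 0.90 (both 100) and T cell genes 0.91 and 1.98 (both 100). NK cell genes (-0.52 and -0.07) and interferon response genes (-0.20 and -0.28) did not share this direction, and stromal genes were lower (-0.46 and -0.73, percentiles 0.65 and 0). Heart muscle genes were lower, by -7.11 and -2.93 for Myl7. The first of these sizes rests on a reading of 6.01 on KA/KA 2, close to background, and depends on the constant as well. Tnni3 was lower by -2.90 on KA/KA 3, and on KA/KA 2 it read background (5.35 against 12.20 on WT 2), so no size is given there. Both comparisons share 1 WT array. The genes at least 2-fold higher on both KA/KA arrays numbered 301 and those at least 2-fold lower 160, of 9097. limma on these 3 arrays, a setting chosen after seeing the data, takes the lone WT array to vary like the KA/KA arrays. It called 0 of 11610 genes higher and 0 lower, with 456 and 290 at an unadjusted p under 0.05 and a smallest adjusted p of 0.745.

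**Figure D3:**
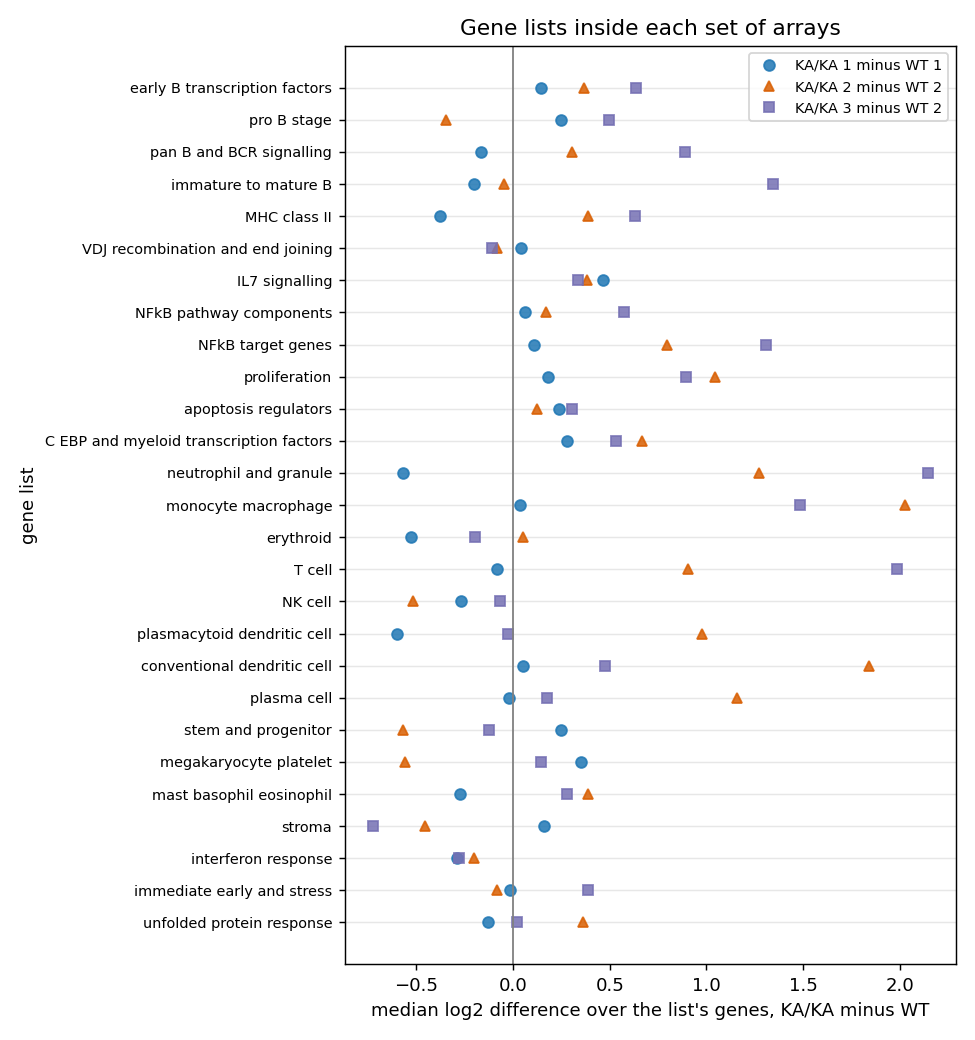
Median log2 difference over the genes of each of 27 lists (x axis; lists on the y axis), for KA/KA 1 minus WT 1 (circles), KA/KA 2 minus WT 2 (triangles) and KA/KA 3 minus WT 2 (squares), 1 array against 1 each. Neutrophil granule genes lie at -0.57 in the high-spike pair and at 1.27 and 2.15 in the low-spike arrays, and interleukin 7 signalling genes at 0.47, 0.38 and 0.34.

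The genotype differences of the 2 sets were weakly and inversely related. Across 11392 genes the KA/KA minus WT difference of the high-spike pair had a Pearson's r of -0.11 (Spearman's rho -0.16) with the mean difference of the low-spike arrays (genes are not independent replicates). In a fit with a term for genotype by array set, which leaves 1 residual degree of freedom, limma called 0 genes (smallest adjusted p 0.754). Camera called 12 lists for that term at the preset correlation and 0 with an estimated correlation (smallest adjusted p 0.703).

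The sex-linked genes were read on each array, with no test of them as a list. The array labelled KA/KA 2 had a female pattern, with Xist at 13.93 and the Y-linked Eif2s3y at 4.78. Arrays labelled WT 1, KA/KA 3 and WT 2 had a male pattern, with Xist at 6.49, 7.22 and 7.67 and Eif2s3y at 11.37, 10.53 and 10.41. The array labelled KA/KA 1 had both, with Xist at 12.48 and Eif2s3y at 10.55, Kdm5d at 9.33 and Uty at 8.02. Over the 5 arrays Xist differed by 4.13 ± 2.10 between the groups (limma, adjusted p = 0.9999), so animals of both sexes were present and unevenly spread over the genotypes.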

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

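The tests of this part were chosen after the results were seen. The poly-A control signal of the array labelled KA/KA 1 was singled out because it is a part of the data that the genotype comparison leaves aside: its median of 11874 stood beside 7301 on the array labelled WT 1 and 46.9 to 249 on the others. It divided the arrays in the same way as the marker genes of B cells and lung. Neutrophil granule genes were singled out because their genotype difference was unlike between the sets, at a median of -0.57 in the high-spike pair against 1.27 and 2.15 on the low-spike arrays. The interaction test of this list gave a camera adjusted p of 1.1e-09 at the preset correlation and 0.703 at an estimated correlation, on 1 residual degree of freedom, the difference between KA/KA 2 and KA/KA 3. As the list was picked for this very contrast, these values describe it and are no independent test.

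The 3 arrays with lung epithelial genes high and Rag1, Dntt, Igll1 and Vpreb1 near background may carry RNA of lung tissue under labels of B220+ marrow cells: 11 of 15 lung epithelial genes were in the top 5% on each of them and on neither other array. The kinase-dead genotype would make KA/KA 1 most like the other KA/KA arrays, but its r with WT 1 was higher by 0.39 than its best r with a KA/KA array (0.578). A labelling batch alone would move lung genes no more than other genes of their level, but they moved by 7.65 against at most 1.55 in random lists. As the lung list was written after the split was seen, its values describe the pattern and are no independent test. How such RNA would have come onto these arrays was not tested.

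Xist and Y-linked genes together on the array labelled KA/KA 1 might come from RNA of female and male animals in 1 preparation: all 3 Y-linked genes lay under those of the male-type array WT 1 (Eif2s3y at 56.6%, Kdm5d at 81.2% and Uty at 80.2% of its level; median log2 difference -0.30), which is the direction a pool of both sexes would give. A probe set that does not measure Xist is an unlikely source, as 3 of 3 Xist probe sets were at least 2-fold above WT 1. The kinase-dead genotype as a cause of Xist would raise it on all KA/KA arrays, but KA/KA 3 stood at -0.45 against WT 2.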

How the results depend on the processing

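No gene was called under nearly every choice. Genes higher in KA/KA numbered 0 and genes lower 0 in all other settings, and with the replicate number as a block 1 gene, Xist, was higher (limma, smallest adjusted p 0.0114). The replicate block pairs KA/KA 1 with WT 1 and KA/KA 2 with WT 2 and leaves KA/KA 3 alone, so the female-type Xist signal of the first 2 KA/KA arrays met male-type partners. After removal of each genotype group's mean from every gene, KA/KA 3 correlated with WT 2 (r = 0.795) more than KA/KA 2 did (0.653). KA/KA 1 correlated with WT 1 (0.877). The 2 WT arrays then mirror each other (r = -1) and the array sets differ widely, so these values cannot tell pairs. The labels do not say that the numbers are pairs, and they were not taken as such.

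The number of called lists moved from 8 to 0 with camera at an estimated correlation and to 0 with fry. It was 16 with the array-set block and 16 on the low-spike arrays alone, both added after seeing the data, and 5 to 15 without single arrays. The other settings called 6 to 12. Of 27 lists, 9 kept their direction in every setting and 18 turned in some; of 52 named genes 28 kept it and 24 turned.

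With the array-set block, several lists turned up: pro-B (camera adjusted p = 0.362), pan-B (0.00688), immature to mature B (0.0725), MHC class II (0.446) and proliferation genes (6.5e-12), with Tcf3 at 0.10 and Vpreb1 at 0.60 log2 units. The replicate block gave the same turn for pro-B (0.829), pan-B (0.675) and proliferation genes (8.9e-09), with Tcf3 at 0.0206 and Vpreb1 at 0.51. On the low-spike arrays alone the lists that turned up were pro-B (0.483), pan-B (0.000276), immature to mature B (0.000106), MHC class II (0.00322), proliferation (5.6e-10), erythroid (0.977) and plasmacytoid dendritic cell genes (0.183); Pcna stood at 0.35, Bcl2l11 at -0.0791, Foxo1 at -0.0591 and Rela at -0.22. None of these 3 settings called any list with an estimated correlation: for proliferation genes the adjusted p was 0.587 with the array-set block, 0.788 with the replicate block and 0.606 on the low-spike arrays, and the last was also the smallest of that setting. In the high-spike pair, values without a test, the genes that turned were Id2 (-0.0730), Ptprc (-0.16), Fcgr2b (-0.19), Lcn2 (-0.59), Lat (-0.0558), Calr (-0.10), Ebf1 (0.57), Pax5 (0.41), Tcf3 (0.61) and Rag1 (0.00979).

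Choices of test, scaling and probe set turned only lists that camera had not called. Array weights turned early B transcription factors (camera adjusted p = 0.0787), neutrophil (0.611), stem cell (0.0803) and stromal genes (0.798). Fry turned pro-B, immature to mature B and stem cell genes (0.998 each). Pro-B genes also turned with the upper-quarter filter (0.913) and with x and s probe sets left out (0.974). Immature to mature B genes turned with quantile normalisation (0.939), every probe set on its own (0.164) and the mean of probe sets (0.828), and MHC class II genes with every probe set on its own (0.970). Stem cell genes turned with median centring (0.938), the floor (0.994), a pseudocount of 1 (0.992), no filter (0.947) and no trend (0.868), and mast cell genes with no filter (0.784). Hbb-b2 stood at 0.47 with x and s probe sets left out, and Mycn at -0.0440 with the mean of probe sets. The cause was not tested.

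Leaving out single arrays gave these ranges of camera adjusted p in lists that turned: early B transcription factors 3.5e-05 to 0.228, pro-B 0.0301 to 0.753, pan-B 1.1e-05 to 0.673, immature to mature B 3.4e-06 to 0.610, MHC class II 0.00038 to 0.890, V(D)J recombination 0.0128 to 0.739, proliferation 4.4e-08 to 0.156, neutrophil 6.4e-12 to 0.389, monocyte 3.0e-13 to 0.845, erythroid 6.1e-05 to 0.325. The range was 0.00828 to 0.654 for NK, plasmacytoid dendritic cell 0.00201 to 0.728, plasma cell 0.00958 to 0.981, stem cell 0.114 to 0.854, megakaryocyte 0.00519 to 0.757, mast cell 0.592 to 0.845, stroma 0.00546 to 0.792 and unfolded protein response 0.297 to 0.925. Log2 differences of genes that turned ranged from -0.0214 to 2.75 for Il7r, -0.51 to 1.30 for Ptprc, -0.0585 to 1.19 for Ciita, -2.29 to 0.91 for Xrcc6, -1.42 to 0.78 for Pcna, -0.22 to 3.46 for Lcn2, -1.79 to 0.0239 for Trim10. They ranged from -2.22 to 0.44 for Ebf1, -1.61 to 0.33 for Pax5, -1.99 to 1.02 for Tcf3, -1.34 to 2.58 for Ikzf1, -0.18 to 0.69 for Foxo1, -0.39 to 1.53 for Spi1, -5.79 to 2.1e-05 for Rag1, -4.97 to 1.76 for Igll1, -5.23 to 3.82 for Vpreb1 and -0.36 to 1.10 for Rela. Of the 8 called lists, only NF-κB targets stayed called without any single array (highest adjusted p 0.0180); the highest was 0.845 for NF-κB components, 0.809 for C/EBP and myeloid factors, 0.227 for conventional dendritic cell, 0.194 for T cell and 0.134 for interleukin 7 signalling genes, with monocyte and erythroid genes as above. Without single arrays Slc7a8 lay between 1.74 and 2.25, Relb between 0.91 and 1.15, Nfkb2 between 0.48 and 0.95 and Ms4a4b between 5.19 and 5.77. The size for Ms4a4b rested on its background-level WT signal: it was 3.46 with a pseudocount of 64 and 4.20 with the floor. With array weights, which leave that signal as it is, the size was 6.01.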

Other observations

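The tests of this part were chosen after the results were seen, apart from the count over arrangements of the labels, whose prediction was written before it was run. The chemokine Ccl8 was among the 26 genes at least 2-fold apart in the same direction in both sets of arrays. The 15 higher ones included the chemokines Ccl8, Ccl12 and Ccl22, the eosinophil granule genes Epx and Prg2, the inhibitory T cell receptor Ctla4, Socs3, Fscn1, Ms4a4b and Slc7a8. On the low-spike arrays Ccl22 was higher by 2.27 and 3.70 log2 units and Ctla4 by 2.84 and 3.33 (KA/KA 2 and 3). On the array labelled WT 1 both read close to background (4.47 and 4.71), so the size of their difference there is not given. The 11 lower ones included Hbb-b2, the basement membrane collagen Col4a3 and the mesothelial gene Upk3b. On the high-spike pair Col4a3 (4.57 and 5.62) and Upk3b (4.37 and 5.98 on KA/KA 1 and WT 1) were close to background. Over the 5 arrays Hbb-b2 stood at 0.47 with x and s probe sets left out.

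A difference by genotype could give such genes, but 4 of 6 arrangements of the labels within the sets, the real one included, gave at least 26 and up to 55, so the count does not tell it from chance. More eosinophils on the KA/KA arrays might give part of them: 3 of 4 listed eosinophil genes were higher on all KA/KA arrays. Epx and Prg2 were among the 26 genes, however, so their direction was fixed by the choice. Of the others, Il5ra stood at 0.75, 0.50 and 0.77 and Siglecf at -0.24, 0.39 and 0.57. On the low-spike arrays Il5ra read 6.28, 6.54 and 5.78, close to background. Siglecf read 9.38, 9.57 and 8.99 there against 6.84 and 7.08 on the high-spike pair, and which cells carried it was not measured. More monocytes and macrophages might also give part of the 26 genes, but in the high-spike pair their list lay at percentile 83.9. Magnetic enrichment for B220 should have removed most cells of both kinds. On both arrays of the high-spike pair, however, 10 of 19 monocyte and macrophage genes lay in the top 5% of probe sets. Of the mast cell, basophil and eosinophil genes 0 of 10 did. The share of such cells was not measured. These sources cannot be told apart here.

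Within the pro-B list, 5 genes of recombination and the surrogate light chain left little trace on the low-spike arrays. Their signal there was close to background, so only upper bounds can be given, with signals raised to at least the 20th percentile of their array (24.8 to 25.7). Relative to the mean of the high-spike pair these were 0.363% for Rag1, 0.548% for Vpreb1, 0.851% for Igll1, 1.10% for Dntt and 2.43% for Rag2. Other genes of that list of 16 varied. Myb read 13.31 and 13.61 on the high-spike pair against 7.93, 9.32 and 9.18, and Spn 10.80 and 10.24 against 7.99, 9.41 and 8.19, while Sox4 read 12.31, 12.10 and 11.90, Cd93 12.30, 13.71 and 13.12 and Kit 10.48, 12.05 and 12.18 (KA/KA 2, KA/KA 3 and WT 2).

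Probe sets without a gene symbol were tested in the same way. Of 2459, limma called 0, with 3 at an unadjusted p under 0.05.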
